A study of Homo sapiens with 9 samples.

How the data were processed

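The data are 1-colour Affymetrix arrays, 9 in all, of RNA from the WA09 human embryonic stem cell line, 3 each from pluripotent cells, cells given DOX for 5 h and cells given retinoic acid for 2 days. Per the labels' protocols, RNA was isolated with TRIzol, biotin-labelled cRNA was prepared from total RNA, and cells were kept either on irradiated mouse embryonic fibroblasts or feeder-free. Per the labels' protocols, retinoic acid at 1 µM was given in medium without added FGF. The deposited table holds log2 values per probe set. Per the submitters' processing notes these were made with RMA and the package affy, whose versions are not given in the sources used here. RMA corrects the background, normalises probes between arrays by quantiles and summarises each probe set by median polish. That the values are on the log2 scale was read from their range, 2.36 to 14.8 with similar medians on every array. RMA sets a floor on dim probe sets that compresses their fold changes, and quantile normalization removes any shift shared by most genes.

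Samples were grouped by their labels, which also number the arrays 1 to 3 within each condition. Of 54675 probe sets, 62 control probe sets were left out of the gene tests. The platform annotation gave exactly 1 gene for 41091 probe sets, several genes for 1801 and none for 11721. Probe sets with several genes or none were not named. Of those with 1 gene, 41037 were matched by Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, and 0 symbols had to be updated. Each gene was represented by the probe set with the highest mean over the 9 arrays, which left 19775 genes. Of these, 10523 had several probe sets. Probe sets of 1 gene were called in opposite directions for 9 genes after DOX and for 1 gene after RA.

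A linear model with the 3 conditions as groups was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes (6 residual and 4.63 prior degrees of freedom), with no filter on low values. Contrasts were DOX against pluripotent, RA against pluripotent and RA against DOX, and a moderated F test covered the 3 conditions. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In addition, 28 gene lists were tested with camera at a preset correlation of 0.01, adjusted over all lists, with an estimated correlation and with fry beside it. The lists covered p53 targets, G2 and M phase genes, G1/S and replication genes, intrinsic apoptosis, DNA repair, immediate-early genes, the integrated stress response, heat shock, NF-κB and cytokines, histones, cholesterol synthesis, core pluripotency, retinoid response, HOX genes of paralog groups 1 to 5 and 6 to 13, neuroectoderm, neural crest, mesoderm, endoderm, trophoblast and amnion, fibroblast and stromal cells, epithelial junctions, targets of FGF and ERK, WNT, BMP and NODAL signalling, ribosomal proteins, and all genes named ZNF with a number. Members counted as measured are those with a probe set of their own among the 19775 genes. Some lists share members. The p53 targets share 3 genes with the apoptosis list and 3 with the DNA repair list, and the pluripotency list shares 4 with the NODAL list.

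The grouping, the tests, the lists, the other settings to try and the rule for named genes were set before the data were examined. The rule takes, for DOX and for RA, the 10 highest and 10 lowest fold changes among called genes whose treated arrays all lie on one side of all pluripotent arrays, up to 4 members with the largest absolute change in each list, and a fixed set of genes with CDKN1A, MDM2, NANOG, SOX2, CYP26A1 and RARB. For RA against DOX it takes the 5 highest, the 5 lowest and the fixed genes, and for genes called in both comparisons the 5 with the largest smaller change in each combination of signs. Some items are not reported here.

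The correlation of the DOX and RA responses was set beside 1000 simulations of unchanged groups that share a simulated control, because shared controls alone give a positive correlation. RNA quality was checked with exact permutation tests on control probe sets. The fit was tested on simulated data with the real genes' means and spreads. For the DOX comparison over 19775 genes it recovered 76.1% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 15 false among 199 calls. For the RA comparison it recovered 82.1%, 100% and 100%, with 11 false among 199 calls. In a simulation for the DOX comparison, camera called the 1 list that had been shifted by 0.5 and 0 of the others among 28. Genes were drawn independently there, so it does not test camera's false calls where members of a list are correlated.

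The alternatives were another choice of probe set per gene (the mean of all, those with the suffixes x_at and s_at left out, or every probe set alone), only genes above the median level, a trended and robust spread, only the 2 compared groups, a further quantile normalization, centring each array, array weights, the replicate number as a block, a 2-fold threshold, and leaving out each compared array in turn. One more, list counts without the third pluripotent array, was chosen after seeing the data. The number of arrays limits the precision. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and plots. The p53 binding data that the series' design names were not analysed here.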

Results

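Gene expression was measured in human embryonic stem cells of the WA09 line, an established pluripotent line, under 3 conditions with 3 arrays each. The pluripotent arrays hold untreated cells. The damage arrays hold cells given DOX (doxorubicin, a topoisomerase II poison that breaks DNA) for 5 h. The differentiating arrays hold cells given retinoic acid (RA, at 1 µM) for 2 days in a medium without added FGF, so they differ from the pluripotent arrays in that growth factor as well. The series asks how the p53 response compares between differentiation and DNA damage. Each of the 9 arrays is a 1-colour Affymetrix array, and its values are normalised log2 intensities. The median probe set lay between 4.62 and 4.68 on every array. After reduction to 1 probe set per gene, 19775 genes were compared, and the small number of arrays limits the precision of every value. Nothing in the labels says that the 3 arrays of a condition came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Which of the cultures described in the protocols (on mouse feeder cells, or feeder-free) gave each array is not stated either.

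Arrays of 1 condition correlated at 0.996 to 0.998 across genes, and no pair among the 36 pairs of arrays held identical values. The leading principal component carried 54.3% of the variance and parted the damage arrays from the rest. The next one carried 19.6%. The third pluripotent array stood somewhat apart from the other pluripotent arrays, and its limma array weight was 0.512 against 1.52 and 1.59 for the others. Control probe sets for the 3′ and 5′ ends of GAPDH and ACTB were compared as a check of RNA integrity, although 3 arrays against 3 cannot give an exact permutation p below 0.1. The 3′ minus 5′ difference of GAPDH shifted by 0.00955 on the log2 scale after DOX (two-sided exact permutation p = 0.7) and by −0.00379 after RA (p = 0.9). Between the RA and DOX arrays it differed by −0.0133 (exact permutation p = 0.7). For ACTB the shifts were −0.184 (exact permutation p = 0.4) and 0.273 (p = 0.4), and between the RA and DOX arrays 0.457 (p = 0.1, the smallest the design allows). Probe sets for 18S ribosomal RNA shifted by 0.387 after DOX (exact permutation p = 0.4) and by −0.0746 after RA (p = 0.9), and differed by −0.461 between the RA and DOX arrays (p = 0.1, again the smallest possible). All fold changes below set 3 treated arrays against 3 pluripotent arrays unless stated otherwise. They are given on the log2 scale with the standard error from limma, and adjusted p-values are limma's after Benjamini-Hochberg adjustment over all genes. No measure of background was used, so where a level in 1 condition lies below the median probe set, it is not shown to be above background and the fold against it may be only a lower bound.

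The first comparison asks what 5 h of DNA damage did to expression in pluripotent cells. Targets of p53 rose strongly and almost as a group. GDF15, a secreted stress-response factor, rose 43.7-fold (log2 change 5.45 ± 0.09 SE, adjusted p = 1.1e-10), from a mean level of 4.92 ± 0.09 to 10.37 ± 0.16 (SD, n = 3 arrays each). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 13.1-fold (3.71 ± 0.12, adjusted p = 1.6e-08), and MDM2, the ubiquitin ligase that limits p53, rose 4.06-fold (2.02 ± 0.09, adjusted p = 1.5e-07). The kinase gene PLK2 rose 16.6-fold (4.06 ± 0.11, adjusted p = 4.4e-09) and the death receptor gene FAS 9.65-fold (3.27 ± 0.11, adjusted p = 2.3e-08), the latter from a pluripotent level of 4.30, below the median probe set. The p53 target list held 37 measured genes, of which 33 rose and 0 fell, 22 of them at least 2-fold. The count adjusted over the list alone was 35 higher and 0 lower. The list as a whole was higher than other genes (camera adjusted p = 6.2e-49). The value for GDF15 rests on 1 of its 3 probe sets. Without probe sets of the suffixes x_at and s_at it was at 0.113 and lost its call (adjusted p = 0.52), and FAS was at 0.309 (adjusted p = 0.037).

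**Figure D1:**
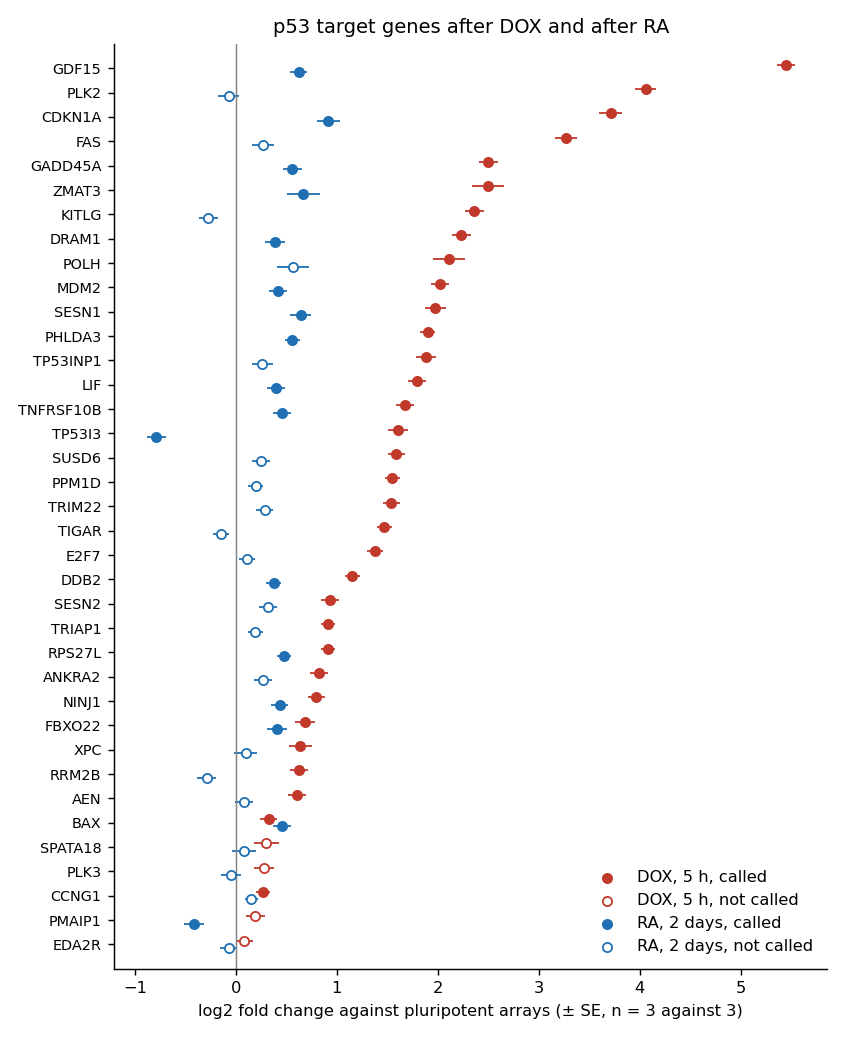
Log2 fold change of each of the 37 measured p53 targets after DOX (red) and after RA (blue), each against the pluripotent arrays, with bars for the standard error and n = 3 arrays per condition. Filled points passed the adjusted p threshold of 0.05 and open points did not. After DOX 33 genes rose and 0 fell, and after RA 15 rose and 2 fell.

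Across all genes, 3019 genes (15.3%) changed after DOX, of which 1121 were higher and 1898 lower. The higher genes moved farther: among changes of at least 2-fold, 246 were higher and 56 lower. For 28.9% of genes the damage arrays all lay on one side of the pluripotent arrays, where chance gives 10%. Of the 3019 called genes 2988 were among these, which being called on the same arrays makes likely. The number of lower genes fell to 1183 without the first pluripotent array (871 higher) and to 1129 without the second (898 higher), and was 2208 without the third (1143 higher). The genes with the highest fold changes included the transcriptional repressor BHLHE40 (4.09 ± 0.19, adjusted p = 1.9e-07), the small MAF protein gene MAFF (4.04 ± 0.19, adjusted p = 1.7e-07), the natriuretic peptide gene NPPB (3.76 ± 0.18, adjusted p = 2.2e-07) and the small GTPase gene RHOB (3.48 ± 0.07, adjusted p = 9.5e-10). RHOB rested on 1 of its 5 probe sets, and with the mean of all probe sets its log2 change was 0.801 and that of BHLHE40 2.21. THBS1, which encodes the matrix protein thrombospondin 1, rose by 3.26 on the log2 scale, a change that 3 of its 7 probe sets showed.

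Immediate-early genes, the transcription factors and feedback genes that cells switch on first after a stimulus, rose with the p53 targets. Of 15 measured members 14 rose and 0 fell, and the count adjusted over the list alone was again 14 higher and 0 lower (camera adjusted p = 1.5e-24). EGR3 rose by 3.46 ± 0.13, FOS by 3.20, JUN by 3.10 (0.736 without x_at and s_at probe sets) and EGR1 by 2.80 on the log2 scale. Targets of the FGF and ERK pathway, which share EGR1 and IER3 with that list, rose in 10 of 15 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 1.2e-08). Their examples were FOSL1 (3.11), IER3 (2.82), PHLDA1 (2.11) and the phosphatase gene DUSP6 (1.38). NF-κB and cytokine genes rose in 5 of 14 cases and fell in 0, with the same counts adjusted over the list alone (camera adjusted p = 4.1e-04), among them CXCL1 (1.31), TNFAIP3 (0.90) and RELB (0.63).

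Mitotic genes fell. Of 26 measured genes of the G2 and M phases 18 fell and 0 rose, and 22 fell and 0 rose in the count adjusted over the list alone (camera adjusted p = 6.2e-14). The spindle checkpoint kinase genes TTK and BUB1 fell by 0.81 and 0.76 on the log2 scale, and PLK1, the kinase that drives mitotic entry, fell by 0.79 (SE 0.14, adjusted p = 0.0033). Genes of the G1/S transition and replication moved both ways. Of 22 measured members 3 rose and 5 fell, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.11), with TYMS at 0.62, CCNE1 at −0.55 and CDT1 at −0.54. Without the first damage array that list was called lower (adjusted p = 0.0398), and without the third pluripotent array 3 of its genes rose and 3 fell. Intrinsic apoptosis genes rose in 5 of 15 cases and fell in 1, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0018, but adjusted p = 0.0502 with an estimated correlation). The apoptosome gene APAF1 rose by 1.16 and the survival gene MCL1, which acts against apoptosis, by 0.65. The lowest values of these 2 genes over the alternatives were 0.48 and 0.47. DNA repair genes rose in 3 of 23 cases and fell in 5, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.11). Their median change was −0.08 while their mean was above 0. The 3 that rose, POLH (2.11), DDB2 (1.15) and XPC (0.64), are also on the p53 target list, and the checkpoint kinase gene ATR fell by 0.57.

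The pluripotency list fell. Of its 23 measured members 9 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0033). FOXD3 fell by 1.12, FGF4 by 0.85 and SOX2 by 0.46 (SE 0.08, adjusted p = 0.0024), while FGF2 and NODAL each rose by 0.90. NANOG changed by −0.15 ± 0.08 and did not pass the test (adjusted p = 0.27). When only genes above the median level were tested, the call on this list was lost (adjusted p = 0.117). The genes with the lowest fold changes after DOX were the neuronal pentraxin gene NPTX1 (−2.05 ± 0.13, adjusted p = 1.7e-06), the opsin gene OPN3 (−1.79 ± 0.11, adjusted p = 2.4e-06), the long noncoding RNA LINC01844 (−1.79 ± 0.15, adjusted p = 1.6e-05), the stress-response gene GADD45G (−1.78 ± 0.17, adjusted p = 4.3e-05) and the HMG-box gene TOX3 (−1.77 ± 0.10, adjusted p = 7.2e-07). LRAT, which esterifies retinol, fell by 1.55, and the histone gene H2AC6 by 1.59.

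Several lineage and signalling lists were higher after DOX. Genes of trophoblast and amnion rose in 7 of 17 cases and fell in 0, or 8 and 0 adjusted over the list alone (camera adjusted p = 1.6e-05). Their examples were EPAS1 (1.53), GATA3 (1.34, on 1 of its 3 probe sets), GATA2 (0.87) and TFAP2A (0.85). Over the alternatives the lowest values of these genes were 0.53, 0.43, 0.34 and 0.32. Genes of fibroblast and stromal cells, fixed as markers of cells other than stem cells that a culture could hold, rose in 6 of 17 cases and fell in 0, with the same counts adjusted over the list alone (camera adjusted p = 9.2e-05). ACTA2 rose by 1.70, TAGLN by 1.59 and COL1A1 by 1.08, with lowest values over the alternatives of 0.70, 1.25 and 0.61. Without the third pluripotent array 4 of these 17 genes rose and 0 fell, a check chosen after that array was seen to stand apart. Whether the rise came from such other cells or from the stem cells was not tested. Targets of BMP signalling rose in 8 of 13 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 1.6e-05, but adjusted p = 0.066 with an estimated correlation), among them the dominant-negative factors ID4 (1.68), ID2 (1.18) and ID3 (1.08). Of the 14 lists called after DOX, 12 higher and 2 lower, 8 kept their call with an estimated correlation. These were the p53 targets, the immediate-early genes, the NF-κB genes, the FGF and ERK targets, the trophoblast and amnion genes and the fibroblast genes, all higher, and the mitotic and pluripotency genes, both lower. A further test, fry, asks whether a list moves on balance without setting it against other genes, and it called 21 lists.

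**Figure D2:**
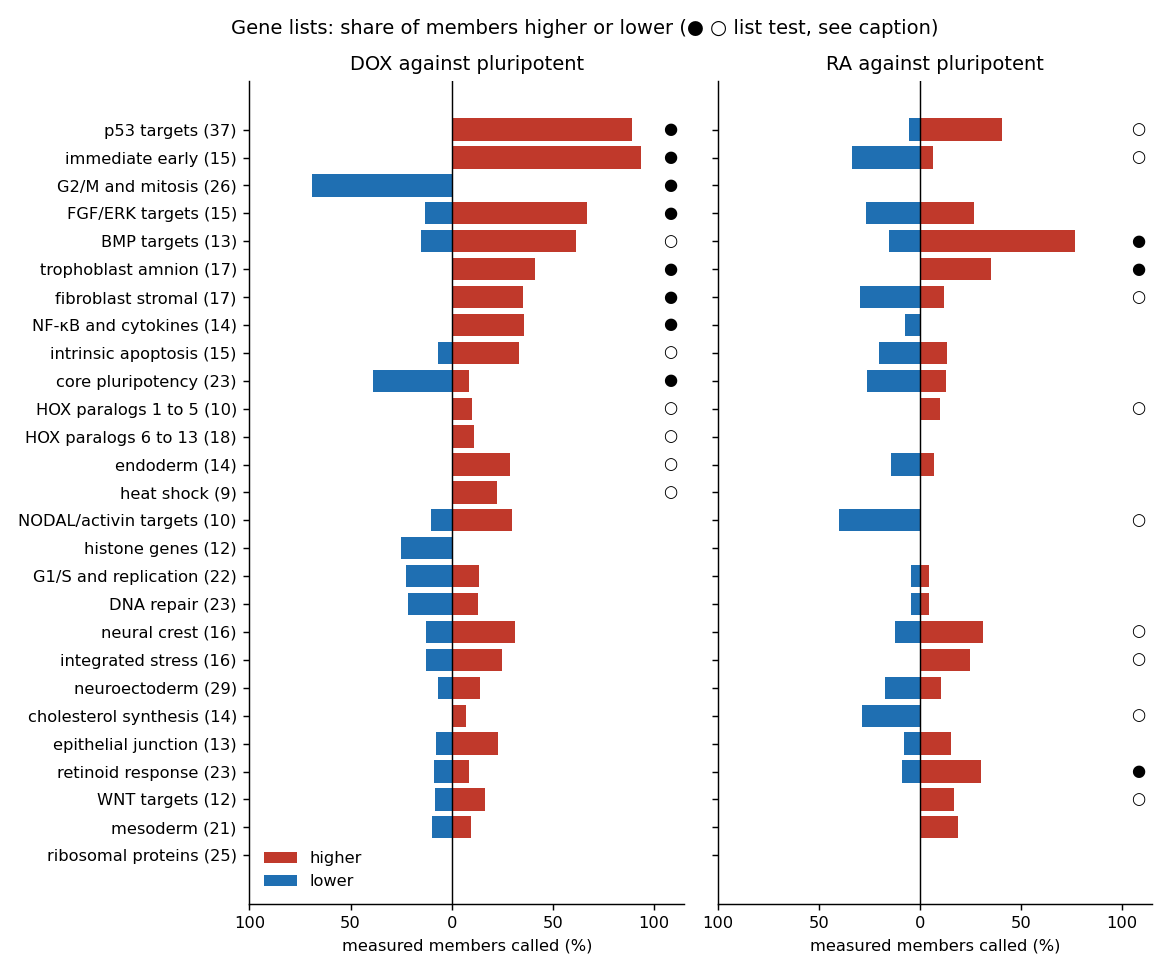
Percentage of measured members called higher (red, to the right) and lower (blue, to the left) in each of 27 gene lists after DOX and after RA. A filled circle marks a list called by camera with both the preset and an estimated correlation, and an open circle a list called with the preset correlation alone. After DOX 8 lists kept their call with an estimated correlation, and after RA 3.

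The next comparison asks what 2 days of RA did. Retinoid-responsive genes rose, as did BMP targets and genes of trophoblast and amnion. ZNF503, a zinc finger repressor, rose 71.9-fold (6.17 ± 0.14, adjusted p = 1.3e-09), from 3.64 ± 0.15 to 9.81 ± 0.22 (SD, n = 3 arrays each), on 1 of its 4 probe sets. That pluripotent level lay below the median probe set, as did those of RARB (4.26), OLIG3 (3.03), ANXA9 (4.45) and HHEX (4.56), so the folds of these genes may be lower bounds. HAS2, which makes hyaluronan, rose 28.7-fold (4.84 ± 0.11, adjusted p = 1.3e-09) and the ectodermal transcription factor gene TFAP2A 23.4-fold (4.55 ± 0.10, adjusted p = 1.3e-09). The homeobox gene MEIS2 rose 18.1-fold (4.18 ± 0.12, adjusted p = 1.2e-08) and the retinoic acid receptor gene RARB 4.63-fold (2.21 ± 0.15, adjusted p = 6.3e-06). The other leading genes were SKAP2 (3.87 ± 0.10), GRHL3 (3.59 ± 0.23), OLIG3 (3.50 ± 0.13), ANXA9 (3.29 ± 0.10), HHEX (3.29 ± 0.22) and GATA3 (3.20 ± 0.19), with adjusted p-values from 3.7e-09 for SKAP2 to 6.3e-06 for HHEX. In all, 1280 genes (6.47%) changed after RA, 624 higher and 656 lower, and 107 rose and 80 fell at least 2-fold. For 22.6% of genes the differentiating and pluripotent arrays did not overlap, against 10% by chance. Without the second pluripotent array 506 genes were higher and 435 lower, and without the second differentiating array 406 and 455. With the mean of all probe sets of a gene the log2 change after RA was 1.55 for ZNF503, 1.65 for TFAP2A and 0.57 for RARB.

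The retinoid list rose in 7 of 23 cases and fell in 2, or 10 and 2 adjusted over the list alone (camera adjusted p = 2.7e-05). Besides MEIS2 and RARB it held CYP26A1, which degrades RA and rose by 1.64 (SE 0.09, adjusted p = 2.2e-06) from an already high level of 10.69 to 12.33, the RA-binding protein gene CRABP2 (1.52) and ZNF703 (1.38). The exceptions were LRAT and RARRES2, which fell by 1.65 and 0.62. Among anterior HOX genes of paralog groups 1 to 5, 1 of 10 measured genes rose and 0 fell, and 2 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0015, but adjusted p = 0.088 with an estimated correlation). That gene was HOXB2, at 1.61. No HOX gene of groups 6 to 13 passed limma's test in either direction among 18 measured, nor adjusted over the list alone (0), nor at an unadjusted p under 0.05 (0), and camera gave an adjusted p of 0.90.

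BMP targets rose after RA, with the smallest camera p of the 28 lists. Of 13 measured targets 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.7e-12). ID4 rose by 2.30, ID3 by 2.22 and the pseudoreceptor gene BAMBI by 1.63, while SMAD7 fell by 0.90 and HEY1 by 0.36. Trophoblast and amnion genes, which share GATA2 and GATA3 with the BMP list, rose in 6 of 17 cases and fell in 0, or 7 and 1 adjusted over the list alone (camera adjusted p = 9.8e-08). GATA2 rose by 1.11, TFAP2C by 1.27 and the keratin gene KRT19 by 0.98. These lists and the retinoid list were the 3 of 12 called lists, 8 higher and 4 lower, that kept their call with an estimated correlation, and fry called 14 lists. Neural crest genes rose in 5 of 16 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0095, but adjusted p = 0.14 with an estimated correlation). Among genes above the median level that call was lost (adjusted p = 0.976). TFAP2A, which is also on the trophoblast and amnion list, and DLX5 (1.88) led the list and ETS1 fell by 0.87. WNT targets rose in 2 of 12 cases and fell in 0, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.030, but adjusted p = 0.16 with an estimated correlation). They were AXIN2 (0.95) and BAMBI, which is also on the BMP list. The WNT list lost its call without the first pluripotent array (camera adjusted p = 0.063).

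Genes downstream of NODAL and activin, the signal that holds human stem cells pluripotent, fell after RA. Of 10 measured genes 4 fell and 0 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 4.8e-05, but adjusted p = 0.068 with an estimated correlation). LEFTY1 fell by 2.63 (SE 0.16, adjusted p = 3.5e-06), NODAL by 1.31 and CER1 by 1.05. The pluripotency list moved both ways. Of 23 members 3 rose and 6 fell, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.33). PRDM14 fell by 1.29 and FOXD3 by 0.86, while FGF4 rose by 1.88. NANOG fell by 0.34 (SE 0.08, adjusted p = 0.036), but passed the test in 0 of the 6 fits that left out 1 compared array, with values of −0.37 to −0.28. SOX2 was at −0.10 and did not pass (adjusted p = 0.62). The genes with the lowest fold changes were LINC01844 (−3.12 ± 0.15, adjusted p = 6.3e-07), the caveolar coat gene CAVIN3 (−3.08 ± 0.25, adjusted p = 2.5e-05), LEFTY1, NPTX1 (−2.62 ± 0.13, adjusted p = 6.8e-07) and CUZD1 (−2.54 ± 0.19, adjusted p = 1.2e-05). The early response gene EGR1 (−2.34 ± 0.16, adjusted p = 5.9e-06) and the ERK phosphatase gene DUSP6 (−2.27 ± 0.19, adjusted p = 3.1e-05) fell as well. These arrays hold cells kept without added FGF.

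**Figure D3:**
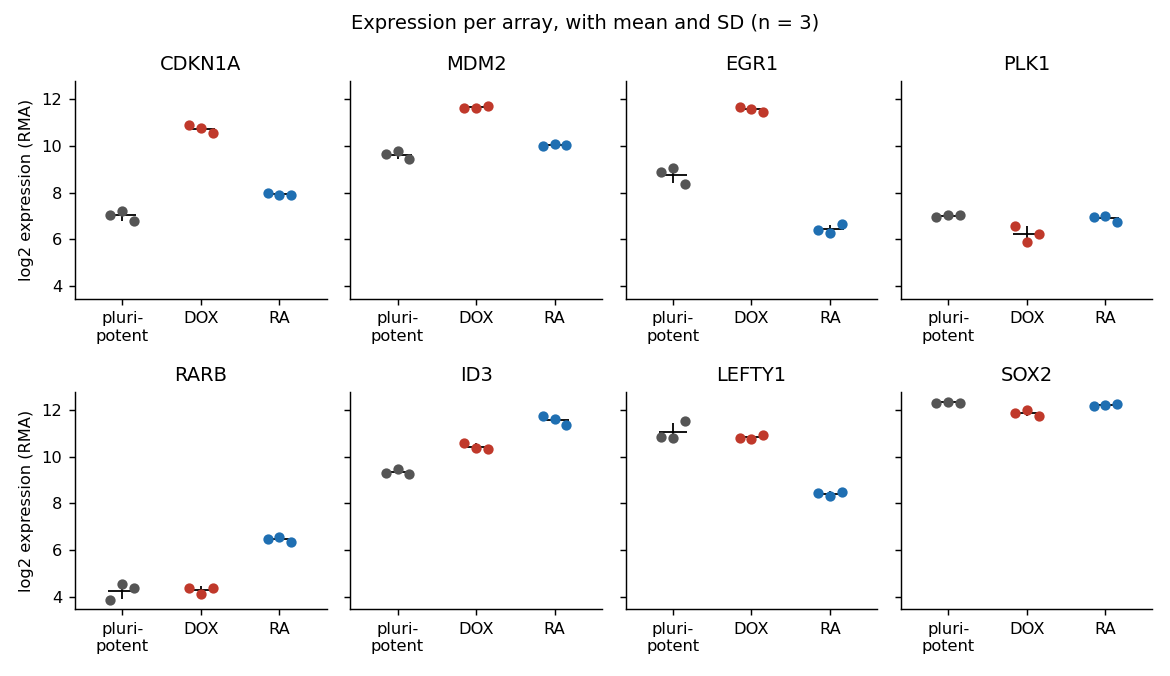
Normalised log2 level of 8 genes on each of the 9 arrays, with the mean and SD of each condition (n = 3 arrays). CDKN1A averaged 7.03 in pluripotent cells, 10.74 after DOX and 7.94 after RA, EGR1 8.77, 11.58 and 6.44, and RARB 4.26, 4.30 and 6.47.

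The p53 targets also shifted after RA, by less than after DOX. Of the 37 measured targets 15 rose and 2 fell, or 24 and 4 adjusted over the list alone (camera adjusted p = 6.7e-09, but adjusted p = 0.12 with an estimated correlation). CDKN1A rose 1.89-fold (0.92 ± 0.12, adjusted p = 0.00063), GDF15 by 0.62 and SESN1 by 0.64 on the log2 scale. MDM2 rose by 0.42 (SE 0.09, adjusted p = 0.016), on 1 of its 10 probe sets. It passed in 4 of the 6 fits that left out 1 compared array, with values of 0.33 to 0.50. The targets that fell were TP53I3 (−0.79) and the apoptosis gene PMAIP1 (−0.42). Immediate-early genes fell in 5 of 15 cases and rose in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 8.0e-04, but adjusted p = 0.22 with an estimated correlation), with JUN at −1.40 (on 2 of its 4 probe sets) and MYC at −0.96. FGF and ERK targets rose in 4 of 15 cases and fell in 4, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.97). SPRED2 rose by 1.16 and PHLDA1 fell by 1.11, and the list's median was just above 0 while its mean was −0.20 and its test pointed lower. Mitotic genes showed 0 calls of limma among 26 in either direction, also adjusted over the list alone (0), with 2 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.54).

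Genes of the integrated stress response rose in 4 of 16 cases and fell in 0 after RA, or 7 and 0 adjusted over the list alone (camera adjusted p = 3.9e-05, but adjusted p = 0.14 with an estimated correlation), with STC2 at 1.27. Cholesterol synthesis genes fell in 4 of 14 cases and rose in 0, with the same counts adjusted over the list alone (camera adjusted p = 4.2e-04, but adjusted p = 0.088 with an estimated correlation), and only 1 fell without the third pluripotent array. Fibroblast genes fell in 5 of 17 cases and rose in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.048, but adjusted p = 0.16 with an estimated correlation). Without the third pluripotent array 2 rose and 3 fell. TAGLN was at −1.76, on 2 of its 3 probe sets, COL6A3 fell by 0.73 and COL1A1 rose by 1.00. The call on this list was lost without the first pluripotent array (adjusted p = 0.064), the third pluripotent array (0.097), the second differentiating array (0.070) or the third differentiating array (0.059), and among genes above the median level (0.067).

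The last comparison sets the 2 responses against each other, which equals testing the RA arrays against the DOX arrays. Treatment times differ as well, 2 days for RA and 5 h for DOX, and the RA cells were kept without added FGF. The design cannot separate these from the effect of the agents. It found 4202 differing genes (21.2%), 2498 higher and 1704 lower after RA than after DOX, with 223 and 301 of them differing at least 2-fold. Some control probe sets moved with this comparison, by 0.457 for the ACTB 3′ minus 5′ difference and −0.461 for 18S ribosomal RNA (exact permutation p = 0.1 each). The GAPDH 3′ minus 5′ difference shifted by −0.0133 (exact permutation p = 0.7). Of the 37 p53 targets 32 were lower after RA than after DOX and 0 higher, or 33 and 0 adjusted over the list alone (camera adjusted p = 1.1e-32). CDKN1A differed by −2.80 ± 0.12 on the log2 scale (adjusted p = 4.9e-08), MDM2 was at −1.60 (adjusted p = 4.2e-07) and GDF15 at −4.83 (adjusted p = 1.4e-10), although GDF15 turned to 0.232 without x_at and s_at probe sets (adjusted p = 0.12). All 15 measured immediate-early genes were lower after RA, over all genes and adjusted over the list alone (camera adjusted p = 1.1e-22), with EGR1 at −5.14 (adjusted p = 6e-09) and JUN at −4.50 (adjusted p = 7e-09), or −0.951 without x_at and s_at probe sets. Of 26 mitotic genes 22 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 6.2e-12). Of 17 fibroblast genes 1 was higher and 9 lower, or 2 and 10 adjusted over the list alone (camera adjusted p = 5.8e-05). Of 13 lists called in this comparison, 3 higher and 10 lower after RA, these 4 kept their call with an estimated correlation, at adjusted p-values of 0.022 for the p53 targets, 0.022 for the immediate-early genes, 0.029 for the mitotic genes and 0.029 for the fibroblast genes. The other 9 lost it, with adjusted p-values of 0.059 to 0.152 with an estimated correlation, among them the BMP, FGF and ERK, NODAL, NF-κB and retinoid lists. The genes most in favour of RA were ZNF503 (6.02), MEIS2 (3.77), SKAP2 (3.74), TFAP2A (3.70) and OLIG3 (3.32). SOX2 was higher after RA than after DOX by 0.36 (adjusted p = 0.0064), and NANOG, at −0.18, did not differ by this test (adjusted p = 0.16).

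Of the genes that passed in both comparisons, 548 in number, 129 were higher after both treatments and 175 lower after both. Independent lists of these sizes would share 35.4 and 63.0. A further 132 were higher after DOX and lower after RA, where independent lists would share 37.2, and 112 were lower after DOX and higher after RA, where they would share 59.9. Genes higher after both included C11orf96 (2.82 after DOX and 2.16 after RA, on 1 of its 2 probe sets), the vasodilator peptide gene ADM (2.33 and 2.14), HAS2 (1.76 and 4.84) and ID4 (1.68 and 2.30). Genes lower after both included NPTX1, LINC01844, TOX3 (−1.77 and −1.96) and SHISA2 (−1.61 and −1.62). EGR1, ANXA1 (1.78 and −1.95), TAGLN (1.59 and −1.76), COL12A1 (1.52 and −1.58) and the caveolin gene CAV1 (1.45 and −2.09) were higher after DOX and lower after RA. In the opposite class were LPAR3 (−0.93 and 1.38), STON1 (−1.22 and 0.91) and FGF4 (−0.85 and 1.88). Of the genes of equal sign, 73 of the 129 higher and 56 of the 175 lower ones differed between RA and DOX in the direct test.

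Across genes, which are not independent replicates, the log2 fold changes after DOX and RA correlated at r = 0.0935, and at 0.160 without the third pluripotent array. Both use the same pluripotent arrays. In 1000 simulations, unchanged groups and a shared control were drawn from each gene's residual spread, and r ran from 0.477 to 0.525. Such draws put r near 0.5 by construction, so they are no yardstick for r where many genes changed. The observed covariance was 0.00749 and the simulated one 0.00524, a difference of 0.00225. The same sign was seen in 56.8% of genes, against 66.7% in simulated unchanged groups, a share likewise set by construction. With 3 control arrays no split leaves a pair in each part, so part of the excess of genes with equal sign over independent lists may come from the shared controls. Genes of opposite sign also exceeded independent lists (132 against 37.2 and 112 against 59.9). Shared controls push toward equal signs, so they do not account for that excess. The figure for independent lists takes every gene as equally likely to be called, which was not tested.

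**Figure D4:**
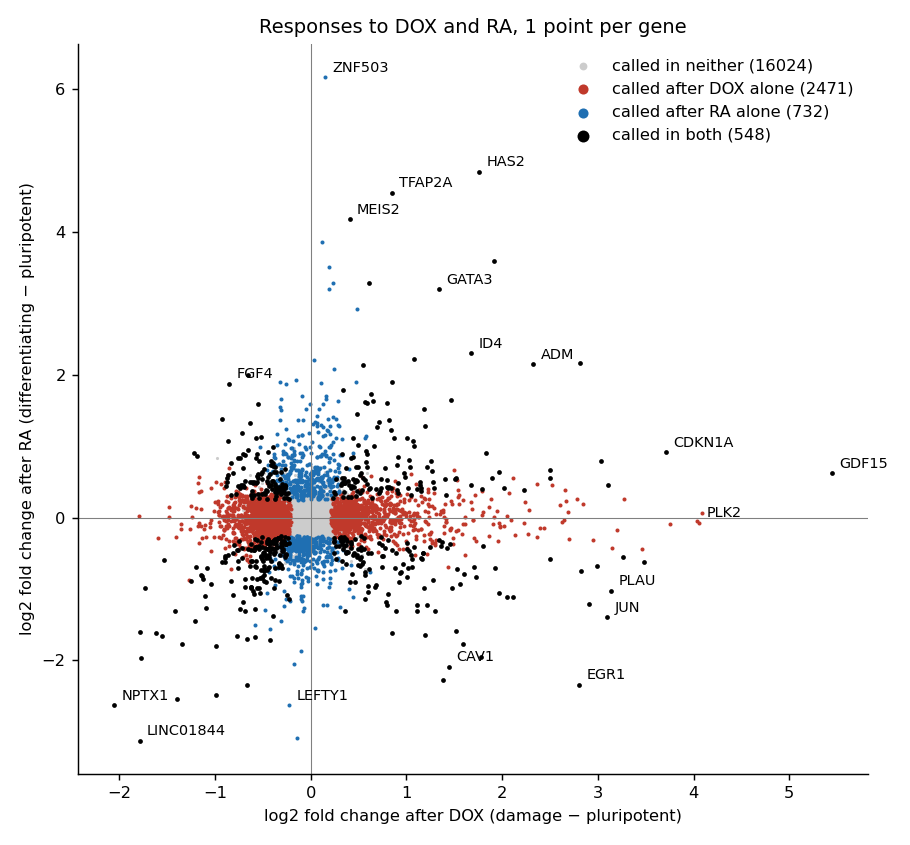
Log2 fold change after RA (vertical) against that after DOX (horizontal) for 19775 genes, each from 3 arrays against the same 3 pluripotent arrays. Colours mark genes called after both treatments (548), after 1 of them or after neither, and the correlation over all genes was 0.0935.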

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

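No test in this part was chosen after its result was seen. Probe sets that name no gene or several genes in the annotation stand outside the gene comparisons, and signal in them is a signal in data the comparisons did not use. There are 13522 such probe sets. Tested in a fit of every probe set, 517 of them passed after DOX, 257 higher and 260 lower, and 159 passed after RA, 88 higher and 71 lower. That is 3.82% and 1.18%, against 8.99% and 3.53% of the probe sets that name 1 gene. Among the passing probe sets, 50.3% were lower after DOX and 44.7% after RA, against 59.7% and 50.8% of the passing probe sets that name 1 gene. Which transcripts they measure was not analysed here.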

How the results depend on the processing

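Of the settings in this part, only the list counts without the third pluripotent array were chosen after the data were seen. The 280 gene results named by rule were recomputed in 4064 alternatives. Of these, 3822 kept their direction and their side of the threshold, 157 lost the call, 64 gained one and 21 turned direction, 6 of them called results. Of the 223 called gene results, 174 kept call and direction in every alternative run. All 6 turns of called results came from leaving out probe sets with the suffixes x_at and s_at, so that another probe set of the gene was used: LDB2 after DOX at 0.00699, APOA1 after DOX at −0.149, ZNF395 after DOX at 0.00895, TAGLN after RA at 0.0513, C11orf96 after RA at −0.125 and GDF15 in RA against DOX at 0.232 on the log2 scale. The other 15 turns were in 9 results that passed in neither fit. They were SC5D (−0.116), RPL7 (0.157) and RPS24 (0.231) after DOX and CDC25C (0.0161) and CXCL2 (0.0987) after RA without x_at and s_at probe sets, RPS24 after DOX (0.0787), HOXB9 after RA (0.0166) and RPL18 after RA (−0.00564) with the mean of all probe sets, RARB after DOX when normalised again (−0.000963) and HSPA4L after RA with array weights (−0.0293). Leaving out 1 array, RARB after DOX ran from −0.153 to 0.172 and HSPA4L after RA from −0.114 to 0.224. Without x_at and s_at probe sets 852 genes passed after RA (445 higher and 407 lower) against 1280, with fewer genes tested. That setting also ended the calls of GDF15 after DOX (0.113), THBS1 after DOX (0.412) and MDM2 after RA (0.373). With the mean of all probe sets per gene, 73.9% of the genes called after DOX and 73.4% of those called after RA kept their call. The size of the change fell by over 1.5 times, or turned, in 76 of 223 called gene results with that mean and in 27 of 179 without x_at and s_at probe sets, FAS (0.309) and JUN (0.736) after DOX among the latter.

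A 2-fold threshold left 302 genes after DOX, 187 after RA and 524 between RA and DOX, by construction. Leaving out 1 array at a time gave 2027 to 3351 genes after DOX, 861 to 1138 after RA, 3189 to 3883 between RA and DOX and 3557 to 4704 among the 3 conditions. It gave 14 to 15 lists after DOX and 10 to 12 after RA. The correlation of the responses ranged from 0.0814 to 0.160, the last without the third pluripotent array. The cause was not tested. An estimated correlation within lists left 8 lists after DOX and 3 after RA. Among genes above the median level 9 lists were called after DOX, where heat shock (adjusted p = 0.052), pluripotency (0.117), HOX groups 6 to 13 (0.121) and endoderm (0.731) were among those lost, with fewer members tested. After RA neural crest (0.976) and fibroblast genes (0.067) were lost and neuroectoderm (0.0324) gained there. Quantile normalization again ended the call on HOX groups 6 to 13 after DOX (0.056). With ACTB in place of GAPDH the RNA quality difference was −0.184 after DOX and 0.273 after RA.

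The replicate number as a block gave 3081 genes after DOX, 1287 after RA, 4296 between RA and DOX and 4435 among the conditions, with 14 and 13 lists, the histone list after RA being called lower under the block (adjusted p = 0.0359). Whether the numbers pair the arrays is not settled. Correlations of the deviations of same-numbered arrays ran from −0.103 to 0.199, and those of differently numbered arrays from −0.247 to 0.133. Most arrays, but not every one, correlated best with an array of their own number. The number of arrays limits what can be called: at a change of 0.5 on the log2 scale, 76.1% of simulated DOX changes were recovered. Dim probe sets near the array's background give compressed changes.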

Other observations

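The counts without the third pluripotent array were chosen after the data were seen, and the other tests here were not. Several gene groups not described so far moved after DOX. Endoderm genes rose in 4 of 14 cases and fell in 0, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.012, but adjusted p = 0.066 with an estimated correlation), led by the secreted NODAL and BMP antagonist gene CER1 at 1.97. Heat shock genes rose in 2 of 9 cases and fell in 0, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.017, but adjusted p = 0.13 with an estimated correlation). They were the chaperone genes HSPA4L (0.98) and DNAJA1 (0.51). HOX genes of groups 6 to 13 rose in 2 of 18 cases and fell in 0, with the same counts adjusted over the list alone, and those of groups 1 to 5 in 1 of 10, or 0 adjusted over the list alone, where 3 were higher and 0 lower at an unadjusted p under 0.05 in limma. Both lists were called (camera adjusted p = 0.011 each, but adjusted p = 0.086 each with an estimated correlation). The call on groups 6 to 13 was also lost when the arrays were quantile-normalised again (adjusted p = 0.056), and the 1 call in groups 1 to 5 was lost without the third pluripotent array. Among genes above the median level, with fewer members tested, 3 of these lists lost their camera call. Their adjusted p-values there were 0.731 for endoderm, 0.052 for heat shock and 0.121 for HOX groups 6 to 13. HOXC6 was at 0.46, HOXB6 at 0.55, passing in 3 of the 6 fits that left out 1 compared array (0.42 to 0.70), and HOXB2 at 0.57, passing in 0 of 6 (0.48 to 0.66).

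Neural crest genes rose in 5 of 16 cases after DOX and fell in 2, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.15), with TWIST1 at 1.41, SNAI2 at 1.02 and NGFR at 0.93. Neuroectoderm genes rose in 4 of 29 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.20), among them DLK1 (1.68, on 1 of its 2 probe sets) and NES (0.94), and without the third pluripotent array 3 rose and 4 fell. NODAL targets rose in 3 of 10 cases and fell in 1, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.087, and 0.0275 without the third pluripotent array). Mesoderm genes rose in 2 of 21 cases and fell in 2 (camera adjusted p = 0.40), WNT targets rose in 2 of 12 and fell in 1 (0.29), with AXIN2 at −0.65 (−0.11 and not called with the mean of all probe sets), and epithelial junction genes rose in 3 of 13 and fell in 1 (0.23), each with the same counts adjusted over the list alone. Retinoid genes rose in 2 of 23 cases and fell in 2 (0.23), and cholesterol genes rose in 1 of 14 and fell in 0 (0.20), also with the same counts adjusted over the list alone. Both higher calls among the retinoid genes were lost without the third pluripotent array. Integrated stress genes rose in 4 of 16 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.18). ATF3 was at 2.69 and DDIT4 at −0.82, and the median of that list was −0.01 while its mean was 0.21 and its test pointed higher. Of 12 histone genes 3 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.11), with H2AC6 at −1.59 and H1-10 at −0.90. Of 25 ribosomal protein genes 0 passed in limma in either direction, adjusted over the list alone or at an unadjusted p under 0.05 (0), after DOX (camera adjusted p = 0.44) or after RA (0.54).

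After RA, histone genes gave 0 calls of limma among 12, with 0 higher and 4 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (camera adjusted p = 0.052). That list was called lower in 5 of 11 alternatives, among them those without the third pluripotent array (adjusted p = 0.016), without the second differentiating array (0.042), with the mean of all probe sets (0.0198) and with centred arrays (0.049). Mesoderm genes rose in 4 of 21 cases and fell in 0, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.56), with BMP4 at 1.67. Without the third pluripotent array 2 rose and 1 fell. Their median was −0.03, while their mean was 0.12 and their test pointed higher. Endoderm genes rose in 1 of 14 cases, HHEX at 3.29, and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.65). Without the third pluripotent array 1 rose and 1 fell. Their mean was 0.11, while their median was −0.03 and their test pointed lower. Neuroectoderm genes rose in 3 of 29 cases and fell in 5, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.44, but called lower among genes above the median level, adjusted p = 0.0324), with IRX3 at 0.83 and the anterior neural gene OTX2 at −1.56. Epithelial junction genes rose in 2 of 13 cases and fell in 1, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.54), with CLDN4 at 1.61. Apoptosis genes rose in 2 of 15 cases and fell in 3, with the same counts adjusted over the list alone (camera adjusted p = 0.65), with HRK at 1.05 and BIK at −0.49. DNA repair genes rose in 1 of 23 cases and fell in 1, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.90), and G1/S genes rose in 1 of 22 and fell in 1, or 1 and 4 adjusted over the list alone (0.37). Both G1/S calls were lost without the third pluripotent array. The repair list had a mean of 0.01 and a test above 0, with a median just below 0. NF-κB genes rose in 0 of 14 cases and fell in 1, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.95), with a median just above 0 and a mean of −0.04. Heat shock genes gave 0 calls of limma among 9, with 0 higher and 2 lower both at an unadjusted p under 0.05 and adjusted over the list alone (0.37).

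More genes were lower than higher after DOX, 1898 against 1121, and 2 hypotheses on the lower ones were tested. The excess of lower calls remained but was smaller when the arrays were quantile-normalised again (1646 lower, 1250 higher) or centred (1694 and 1252). Part of it thus depends on how the arrays were scaled. Neither setting can restore a shift shared by most genes that RMA removed. Without the first pluripotent array the counts were 1183 lower and 871 higher, without the second 1129 and 898, and without the third 2208 and 1143. Leaving out a damage array gave 1709 and 1083, 1436 and 1005 or 1428 and 962, so lower calls outnumbered higher ones in all 6 fits but by amounts that varied with the array. One hypothesis was that long genes fell more because doxorubicin may hinder transcript elongation. Genomic span, from assembly GRCh38.p14, was known for 19730 genes (99.8%). Its Spearman correlation with the DOX log2 change over genes was −0.0965 (−0.128 to −0.0725 when 1 array was left out), against 0.0505 for RA. The median span was 39.6 kb for genes lower after DOX, 25.0 kb for those higher and 23.5 kb for those not called, while after RA it was 36.6 kb for lower and 42.7 kb for higher genes. The value lay between the bounds set before the test, −0.1 and −0.05, so the hypothesis stays open. Level also differs with span. Among genes above the median level the correlation was −0.0969 for DOX and 0.108 for RA.

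The other hypothesis was that short-lived transcripts of ZNF genes, many of which encode repressors, may fall as a group when synthesis is reduced. Of 425 measured ZNF genes 49 fell and 20 rose after DOX, or 50 and 24 adjusted over the list alone (camera adjusted p = 0.18). Their median change lay −0.0361 from that of all genes (−0.0639 to −0.0264 when 1 array was left out). By the bound set before the test, a median above −0.05 counts against the hypothesis, and −0.0361 lay above it. The range when 1 array was left out crosses that bound, so the test does not decide and this hypothesis stays open too. Without the third pluripotent array 68 ZNF genes fell and 22 rose after DOX, while the lower calls over all genes also rose, to 2208. After RA 11 ZNF genes rose and 4 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.57), with a median just below 0 and a mean of 0.03. Without the third pluripotent array 9 rose and 8 fell.

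Other splits of the arrays were counted. For the 3 pairwise comparisons 3 arrays against 3 give 10 splits, too few for a share under 0.05. Fitted on the 2 compared groups, 1 of 10 splits, the real one, reached the real count in each: 2490 genes after DOX, 1109 after RA and 3979 between RA and DOX, with 0 as the highest of the other splits. For the F test among the 3 conditions 1 of 100 drawn splits, the real one, reached its 4377 genes. This speaks only against a random division of these arrays. It cannot exclude chance differences between cultures, since separate cultures are not shown. Splits that mix conditions also carry condition differences in their residual spread, which lowers their counts. The highest other split gave 2113 genes. The 6 splits that kept the damage arrays together gave 2023 to 2113 genes, the 1 that kept the differentiating arrays together gave 675, and the 92 that kept no condition together gave 0 each.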
